A study of Mus musculus with 6 samples.

How the data were processed

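RNA from 3T3-L1 cells was sequenced at day 0, undifferentiated, and at day 7 of adipocyte differentiation, with 3 libraries per day. Libraries were made with the Illumina Stranded Total RNA Prep and read on an Illumina NovaSeq instrument, per the labels' protocols. Trim Galore 0.6.7, STAR 2.7.10a and Salmon 1.9.0 were used with genome build GRCm38, per the submitters' processing notes. The role of each tool, the annotation release and any filter are not given in the sources used here. The deposited table gives an estimated count per gene and library, not scaled to a common total. This unit was read from the values, most of them whole and the rest with up to 3 decimals. A side block of 10 columns beside the table was not used.

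The table held 43760 rows. Of its names, 85 stood on more than 1 row, 198 rows in all, and these rows were kept apart under numbered names. Dates stood in place of gene symbols on 21 rows. In GENCODE M21, the GRCm38 annotation used for gene locations and lengths, 40088 row names were found once and 3414 were not found. The 3 day 7 columns all carry replicate number 1 in the file header, so they are called the first, the second and the third day 7 column.

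Counts were rounded to whole numbers. Genes were filtered with filterByExpr (at least 10 counts in enough libraries and 15 in total) and libraries scaled by TMM, with factors from 0.778 in the second day 7 column to 1.14. Days were compared by edgeR's quasi-likelihood test with group as the only factor, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as threshold. The biological coefficient of variation was 0.186. Levels are TMM-scaled CPM, given as mean and SD of 3 libraries, and the error of a log2 fold change is its standard error, taken as its size over the square root of the F statistic. Where a gene had no count in a group, the fold is a lower bound from a floor of 3 counts over that group. Where it had 1 to 3 counts, the ratio of counts is given with an exact binomial 95% interval. These bounds and intervals cover counting error only. Counts that were not whole, by more than 0.01, in at least 1 library were found for 1860 tested genes, and the number of such libraries is given for named genes with fractional counts in at least 4 of 6, whose values are uncertain where reads were shared with close copies.

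Gene lists, 50 in all, were written from general knowledge before the files were opened. Of 1485 entries 1468 matched a row, 6 of them through a RefSeq synonym, 2 fell on several rows and were not used, and 15 were not found. Lists with at least 5 tested members, 44 of them, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted together by Benjamini-Hochberg. Camera tests a list against the other genes, while fry, run beside it, tests a list against no change, so their p-values answer different questions. The RNA-binding protein genes are the union of the RNA-binding protein families without cytosolic ribosomal proteins and metabolic enzymes, 636 genes matched to a row, and were compared with all other tested genes by Fisher's exact test. Counts of changed members come from the adjustment over all genes, and a second count is adjusted over the list alone, printed where it differs.

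Named genes followed a rule written before the files were opened. It names Pparg, Cebpa, Fabp4, Adipoq, Plin1 and Dlk1 whatever their result. It names the 5 genes that rose most and the 5 that fell most past the threshold, with a mean of at least 10 CPM, an official symbol and groups that do not overlap. It names the same for RNA-binding protein genes with no minimum level, and for each list the 2 members most changed in the main direction and the 1 most changed in the other. Some genes that this rule names are not reported here. Members named to spell out counts of 5 or fewer, Ptrf, Arntl, the genes in the opening of the other observations and the genes named for the third day 7 column were chosen after their values were seen.

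The scripts were tested on simulated counts for the comparison of day 7 with day 0, with 200 of 12202 genes changed. Of 100 genes changed 2-fold 69 were recovered, and of 100 changed 4-fold 97, with 3 false calls. A shifted list was called by camera, by fry and with an estimated correlation, and 0 of 43 other lists were called by camera. Each simulated gene was drawn independently, and few genes changed. The simulation thus does not show how camera behaves with many changed genes. Nor does it cover correlated lists, such as cytosolic ribosomal proteins with an estimated correlation of 0.69 in the data.

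Depth ran from 7655822 to 16987076 counts per library. Outside the 10 most abundant rows, 3969822 to 9459808 counts were left, so genes near the filter rest on few counts. Alternatives were RLE, upper-quartile and total-count scaling, no filter and a filter of 10 CPM in 3 libraries, DESeq2 and limma-voom, a test against a 2-fold change (glmTreat), removal of mitochondrially encoded genes and the 10 most abundant rows, each library left out in turn, an estimated correlation in camera, fry, a comparison with genes matched on expression and a wider union of RNA-binding protein genes. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. Splicing, transcript isoforms and protein levels were not analysed here.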

Results

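RNA sequencing measured gene expression in 3T3-L1 cells, a mouse fibroblast line that turns into fat-storing adipocytes when given a hormonal cocktail. Cells were taken undifferentiated (day 0, 3 libraries) or after differentiation with IBMX, insulin, dexamethasone and rosiglitazone (day 7, 3 libraries). Total estimated counts ranged from 7655822 in the third day 7 column to 16987076 in the first. A few rows held much of the depth: the rows named Yam1 together took 27.3% to 38.2% of a library, and counts outside the 10 most abundant rows ranged from 3969822 to 9459808. Every pair of libraries of a group differed by more than sampling noise, with chi-square values per gene of at least 6.72, so each was counted as 1 replicate. Along the first axis of a multidimensional scaling plot the days separated, with 79.7% of the variance. The second axis, with 10.7%, set the third day 7 column at 1.81 apart from the first at -0.62 and the second at -0.99. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

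The comparison of day 7 with day 0 asks which genes differ between differentiated and undifferentiated cells, with RNA-binding proteins as the study's subject. Differentiation, exposure to the cocktail and time in culture differ together between the days, so their effects cannot be told apart. The adipocyte program rose and the preadipocyte gene Dlk1 fell. Pparg, the nuclear receptor that drives fat cell formation, rose 12.7-fold, from 13.5 ± 1.44 to 171 ± 31.5 CPM (SD, n = 3 per day; log2 fold change 3.67 ± 0.17, SE; edgeR adjusted p = 5.3e-06). Cebpa, its partner transcription factor, rose 12.3-fold to 173 ± 50.4 CPM, and Fabp4, a fatty acid carrier of adipocytes, rose 456-fold from 4.61 ± 0.464 to 2100 ± 607 CPM. Adipoq, which encodes the hormone adiponectin, had 2 counts over the day 0 libraries and 41208 over those of day 7, a ratio of 23350 (95% counting interval 6465 to 192800). Plin1, a lipid droplet coat protein, had 1 count against 12118, a ratio of 13740 (2465 to 542600). The day 0 counts of each came from 1 library. Dlk1, an inhibitor of adipogenesis, fell from 1667 ± 44.1 to 146 ± 102 CPM (log2 fold change -3.52 ± 0.53, edgeR adjusted p = 0.00082), and to -4.19 without the third day 7 column. In the GRCm38 annotation, Pparg lies on chromosome 6 at 115360951 to 115490399, Cebpa on chromosome 7 at 35119293 to 35121928, Fabp4 on chromosome 3 at 10204088 to 10208576, Adipoq on chromosome 16 at 23146536 to 23158028, Plin1 on chromosome 7 at 79720218 to 79732903 and Dlk1 on chromosome 12 at 109452823 to 109463336.

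**Figure D1:**
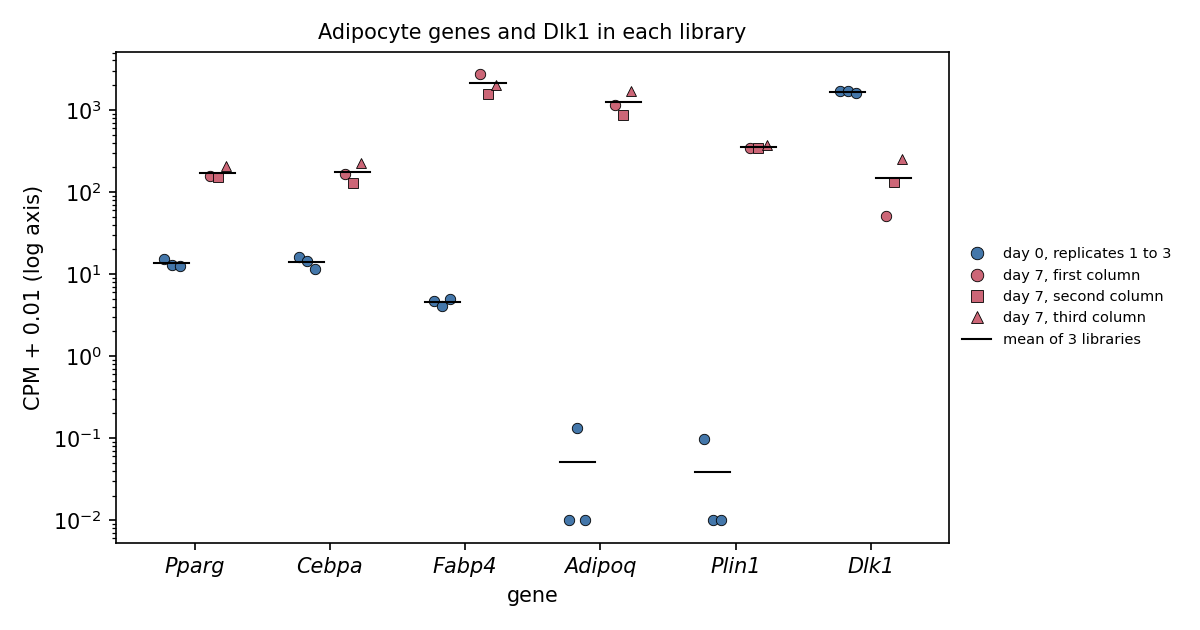
Expression of 6 genes in each of the 6 libraries, as CPM plus 0.01 on a log axis, with blue points for day 0, red points for day 7 (the marker shape gives the column) and a line at the mean of each day. Pparg, Cebpa, Fabp4, Adipoq and Plin1 lie higher in every day 7 library than in any day 0 library, and Dlk1 lies lower.

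Across the transcriptome, 3802 genes rose and 3611 fell of 12354 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 1979 rose and 2184 fell by at least 2-fold, and 300 rose and 313 fell by at least 10-fold. The groups did not overlap for 8434 genes, 68.3% of those tested, where chance gives 10% for 3 against 3 libraries, whose smallest exact p is 0.1. With libraries scaled by total counts alone, 2355 genes rose and 4025 fell, 36.9% of changed genes rising against 51.3%, and the median log2 fold change of all genes moved from 0.02 to -0.21.

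Among genes with a mean of at least 10 CPM, those that rose most were adipocyte genes. Besides Adipoq, they included Cidec, a protein that fuses lipid droplets, Cfd, the secreted protease adipsin, and Slc2a4, the insulin-responsive glucose transporter. Cidec and Slc2a4 had no counts at day 0 and were at least 10570-fold and 1902-fold higher at day 7, from a floor of 3 counts over the group. Cfd had 1 count against 20197, a ratio of 22890 (95% counting interval 4108 to 904200). The genes that fell most were Oas2, Grpr, Oas1a, Cxcl5 and Ces1g. Oas2 and Oas1a encode enzymes that sense double-stranded RNA, Grpr a receptor for gastrin-releasing peptide, Cxcl5 a chemokine and Ces1g a carboxylesterase. Oas2 went from 62.8 ± 3.67 to 0.664 ± 0.582 CPM, and Cxcl5 from 1038 ± 152 to 18.6 ± 30.5 CPM (log2 fold change -5.87 ± 1.46, edgeR adjusted p = 0.0093). The third day 7 column held 396 of the Cxcl5 counts, against 14 and 11 in the others, and without it the log2 fold change was -10.13. Without that column, Grpr moved from -6.15 to -7.52 and Ces1g from -5.84 to -8.39.

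Lipid storage and mitochondrial energy genes rose together. Of 32 tested lipid droplet and mature adipocyte markers, 31 rose and Ptrf, at 426 ± 20.8 and 465 ± 86.1 CPM, did not pass (median log2 fold change 6.05; camera adjusted p = 1.4e-36, and adjusted p = 0.038 with an estimated correlation). In fatty acid and triglyceride synthesis, 24 of 27 rose (median 3.46; camera adjusted p = 4.1e-24, and adjusted p = 0.016 with an estimated correlation), led by Thrsp, a regulator of lipogenesis with 1 count at day 0 and 5587 at day 7 (ratio 6333, 95% counting interval 1136 to 250200), and by Gpd1, which makes glycerol 3-phosphate, from 0.541 ± 0.181 to 792 ± 318 CPM. These are the lists whose calls held with an estimated correlation. In lipolysis and fatty acid oxidation, 28 of 30 rose (median 2.23; camera adjusted p = 6.2e-21, but adjusted p = 0.12 with an estimated correlation). G0s2, an inhibitor of the lipase ATGL, went from 0.345 ± 0.0925 to 120 ± 33.5 CPM, and Acaa1b, a peroxisomal thiolase, from 1 count to 89 (ratio 100.9, 95% counting interval 17.65 to 4029), with fractional counts in 4 libraries. Acaa1b was uneven at day 7, at 0.964, 3.05 and 5.84 CPM, and its log2 fold change moved from 6.44 to 8.29 without day 0 replicate 3. Cpt1a, which moves fatty acids into mitochondria, fell 5.91-fold from 59.6 ± 3.88 to 10.1 ± 1.56 CPM. Cholesterol synthesis had 21 of 22 members higher (median 2.97; camera adjusted p = 8.4e-10, but adjusted p = 0.35 with an estimated correlation), with Insig1, a sterol sensor, up 22.0-fold and Fdps, an isoprenoid synthase, up 14.9-fold, a value uncertain for its fractional counts in all 6 libraries. Among 24 genes of the tricarboxylic acid cycle and pyruvate carboxylation, 23 rose (median 2.17; camera adjusted p = 2.2e-20, but adjusted p = 0.20 with an estimated correlation), Pcx, pyruvate carboxylase, by 26.1-fold and Idh3a by 12.3-fold.

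All 52 tested nuclear-encoded genes of oxidative phosphorylation rose (median log2 fold change 1.62; camera adjusted p = 5.7e-18, but adjusted p = 0.35 with an estimated correlation). Those with the highest fold changes were Cox8b and Cox7a1, cytochrome oxidase subunits of muscle and brown fat, with 0 and 2 counts at day 0 and 65 and 349 at day 7. Cox8b was at least 24.6-fold higher and Cox7a1 had a ratio of 197.8 (95% counting interval 54.34 to 1640). Of 13 mitochondrially encoded genes 11 rose, 12 when adjusted over the list alone (median 1.58; camera adjusted p = 0.00016, but adjusted p = 0.32 with an estimated correlation), with mt-Nd6 up 9.25-fold and mt-Nd2, with fractional counts in 4 libraries, up 4.45-fold. Mitochondrial ribosomal RNA went from 2.17% ± 0.120 to 8.22% ± 2.43 of counts (SD, n = 3 per day). In the peroxisome list 24 of 28 rose, 25 when adjusted over the list alone (median 1.62; camera adjusted p = 3.1e-11, but adjusted p = 0.11 with an estimated correlation), among them the membrane channel gene Pxmp2 and Gnpat, an enzyme of ether lipid synthesis with fractional counts in 3 libraries that went from 13.9 ± 0.952 to 156 ± 6.95 CPM. Without the third day 7 column the log2 fold change of Pxmp2 moved from 4.40 to 3.72. Far1, of the same pathway, fell 1.73-fold. Of 21 thermogenic fat genes only 11 were tested, and 9 of these rose (median 2.97, camera adjusted p = 0.00046, but adjusted p = 0.16 with an estimated correlation). Cox7a1 and Cox8b stand in this list too. Levels were low: Ucp3 and Elovl3 had no counts at day 0 and were at least 61.6-fold and 73.3-fold higher at day 7, with 163 and 194 counts. The first day 7 column held 170 of the Elovl3 counts, and without it the log2 fold change moved from 8.78 to 6.97. Tmem26, used as a beige fat marker, went from 61 counts to 2, both in the third day 7 column (ratio 26.91, 95% counting interval 7.137 to 227.2), and Tnfrsf9 fell. Without the day 0 replicate 2 the median of this list was 4.48.

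Regulators of adipogenesis and of insulin action went both ways. Of 24 adipogenic transcription factors 15 rose and 6 fell (median log2 fold change 0.72; camera adjusted p = 5.6e-05, but adjusted p = 0.20 with an estimated correlation). Mlxipl, the glucose-responsive factor ChREBP, had no counts at day 0 and was at least 407-fold higher at day 7, Klf15 rose 136-fold and Klf4 fell 4.14-fold. The log2 fold change of Klf15 moved from 7.08 to 7.70 without day 0 replicate 3. In insulin signalling and glucose uptake 14 of 25 rose and 6 fell (median 0.92; camera adjusted p = 4.3e-05, but adjusted p = 0.11 with an estimated correlation). Slc2a4 and Pde3b, the insulin-activated phosphodiesterase that went from 1.98 ± 0.423 to 221 ± 14.6 CPM, rose most, and Grb14, an inhibitor of the insulin receptor, fell 5.81-fold. Among 16 circadian clock genes 10 rose and none fell (median 1.02; camera adjusted p = 0.0077, but adjusted p = 0.32 with an estimated correlation), among them Bhlhe40, up 4.21-fold. Of the other 6, Arntl lay lowest, at 16.3 ± 1.67 and 11.3 ± 3.13 CPM with an edgeR adjusted p of 0.067.

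Preadipocyte, matrix, actin and cell cycle genes fell. Of 23 adipogenesis inhibitors and preadipocyte genes 15 fell (median log2 fold change -1.51; camera adjusted p = 0.00013, but adjusted p = 0.46 with an estimated correlation), with Wnt6, a ligand that blocks adipogenesis, 45.9-fold lower and Gata2 going from 13.3 ± 1.08 to 0.932 ± 1.09 CPM, while Tgfb1 rose 1.92-fold. Without the third day 7 column the log2 fold change of Gata2 moved from -4.17 to -5.62. In the collagen and fibrillar matrix list 23 of 32 fell (median -1.56; camera adjusted p = 3.8e-07, but adjusted p = 0.32 with an estimated correlation), with the matrix proteins Fbln1 27.4-fold and Mfap5 23.6-fold lower, and Col5a3 and Col6a3 rose. Of 25 actin cytoskeleton and contractile genes 23 fell (median -2.11; camera adjusted p = 5.8e-11, but adjusted p = 0.12 with an estimated correlation), such as Myl9, a myosin light chain, from 27.5 ± 0.963 to 0.962 ± 0.541 CPM, and Actg2, smooth muscle actin, from 7.67 ± 1.23 to 0.192 ± 0.204 CPM. Myh10, a nonmuscle myosin with fractional counts in 5 libraries, rose 2.86-fold. Without the second day 7 column the log2 fold change of Actg2 moved from -5.18 to -5.91.

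Of 46 cell cycle and DNA replication genes 42 fell (median log2 fold change -2.15; camera adjusted p = 4.9e-11, but adjusted p = 0.35 with an estimated correlation). Ccnd1, cyclin D1, fell 15.4-fold from 283 ± 14.7 to 18.7 ± 10.9 CPM, Mcm5, part of the replicative helicase, fell 8.89-fold, and Ccne2 rose 1.73-fold. Without the second day 7 column the log2 fold change of Mcm5 moved from -3.15 to -3.84. Replication-dependent histone genes went the same way, 18 of 22 lower (median -1.42; camera adjusted p = 9.0e-05, but adjusted p = 0.46 with an estimated correlation), with Hist2h3c2 14.6-fold and Hist1h3b 11.6-fold lower and Hist1h2bc and Hist1h1c higher. Counts were fractional in 5 libraries for Hist2h3c2 and in all 6 for the other 3, so reads may be shared among near-identical copies. Cell cycle inhibitors were divided, with 4 of 14 higher and 5 lower (camera adjusted p = 0.96): Cdkn2c rose 4.91-fold, while Gadd45b fell from 10.3 ± 0.898 to 1.16 ± 0.72 CPM and Cdkn2b fell 3.17-fold.

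Interferon and inflammatory genes were high in undifferentiated cells and low at day 7. Of 34 interferon-stimulated genes 33 fell (median log2 fold change -3.12; camera adjusted p = 7.0e-19, but adjusted p = 0.32 with an estimated correlation). Their summed level went from 4503 ± 221 to 1202 ± 478 CPM (SD, n = 3 per day). Oas2 and Oas1a fell most, and Ifi27, the exception, rose 4.39-fold. Of 22 chemokines and inflammatory genes 15 fell and none rose (median -2.32; camera adjusted p = 0.00038, but adjusted p = 0.64 with an estimated correlation). After Cxcl5 the most changed was Il6, from 3.98 ± 1.52 to 0.245 ± 0.377 CPM. The third day 7 column held more of these transcripts: its list median against the day 0 mean was -1.46 for chemokines, against -3.83 and -3.76 in the others, and -2.33 for interferon-stimulated genes, against -3.66 and -3.70. Without it the chemokine median was -4.05, and Il6 moved from -4.39 to -6.45.

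**Figure D2:**
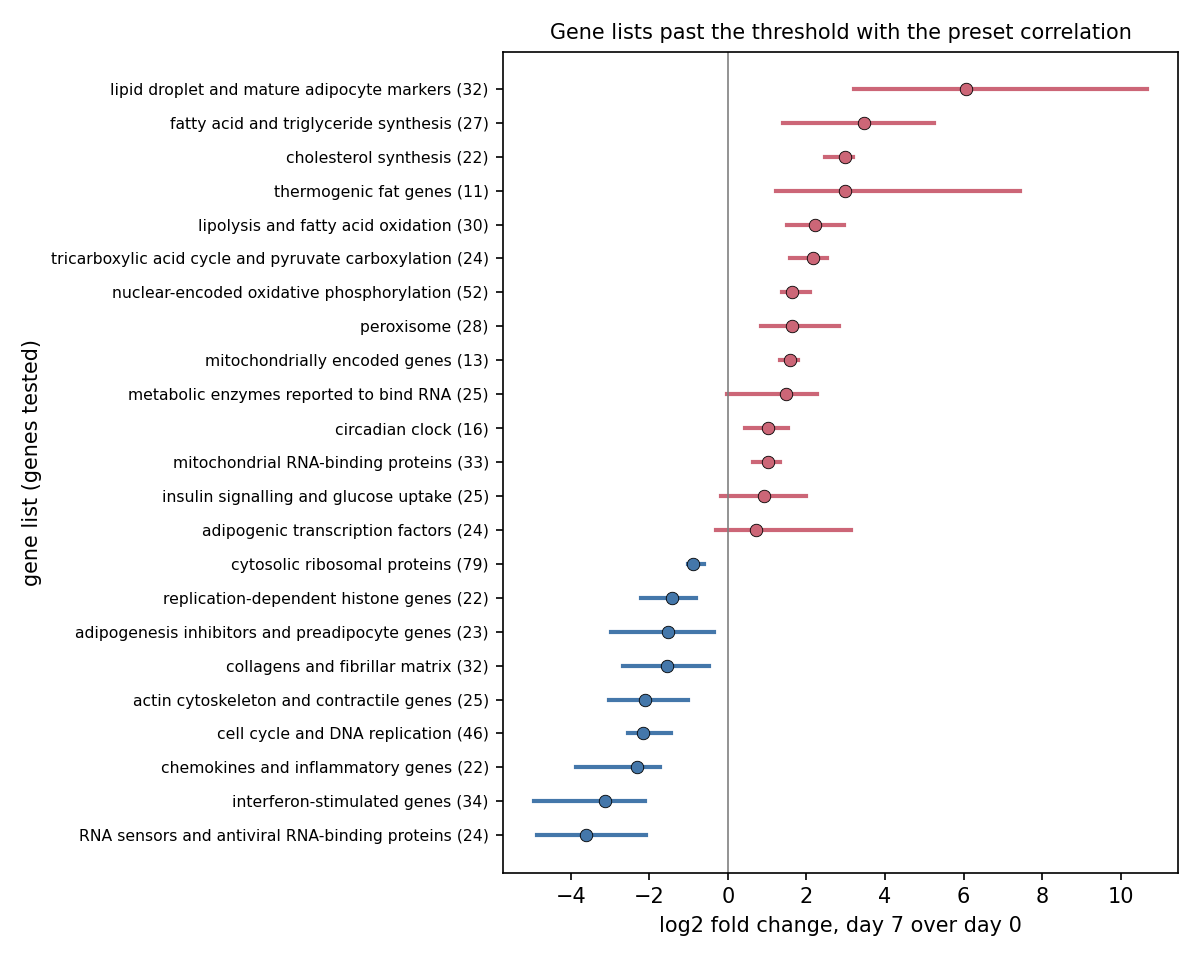
Median log2 fold change at day 7 over day 0 (points) and the range between quartiles (lines) for the 23 gene lists past the camera threshold with the preset correlation, with the number of genes tested in brackets. Lipid droplet and mature adipocyte markers stand highest at 6.05, and RNA sensors and antiviral RNA-binding proteins lowest at -3.61.

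RNA-binding protein genes changed in both directions, and less often than other genes. Of 601 tested members of the RNA-binding protein families, 172 rose and 138 fell, or 163 and 134 adjusted over the list alone. They changed in 51.6% of cases against 60.4% of 11753 other genes (odds ratio 0.697, 95% interval 0.590 to 0.825, Fisher's exact p = 1.9e-05). This call turns around without the filter on low counts (odds log2 0.50 against -0.52), where 20807 genes were tested. Fisher's test treats genes as independent, but they were measured in the same 6 libraries and may move together. Its p-values and intervals here and below thus do not measure the spread between samples. At least 2-fold changes were seen in 40 that rose and 42 that fell, and 22 of the latter were RNA sensors. The balance of rises and falls did not differ detectably from that of other genes (odds ratio 1.19, 95% interval 0.943 to 1.51, Fisher's exact p = 0.13). It turned with the scaling: by total counts alone, 65 rose and 155 fell (log2 odds -0.50, Fisher's exact p = 0.023). Leaving out day 0 replicate 1 left 112 that rose. Leaving out the third day 7 column gave 203, and the balance then leaned to rises (log2 odds 0.43, Fisher's exact p = 0.0063).

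The RNA-binding protein genes that rose most were Rbm47, Tob1, Rbpms2, Cpeb4 and Tfb1m. Rbm47, a splicing and RNA editing cofactor, rose 44.2-fold from 0.526 ± 0.339 to 23.1 ± 6.37 CPM (log2 fold change 5.46 ± 0.38, edgeR adjusted p = 2.1e-05), or 6.08 on the log2 scale without day 0 replicate 3. Tob1, an antiproliferative protein that recruits the deadenylase complex, went from 36.8 ± 3.41 to 231 ± 64.2 CPM (2.65 ± 0.21, adjusted p = 3.7e-05). Rbpms2, which binds mRNA in smooth muscle, rose 5.64-fold to 11.4 ± 1.51 CPM. Cpeb4, which binds the cytoplasmic polyadenylation element, rose 4.57-fold from 25.5 ± 1.86 to 117 ± 9.06 CPM (2.19 ± 0.11, adjusted p = 7.5e-06). Tfb1m, which methylates mitochondrial ribosomal RNA, rose 3.99-fold to 6.20 ± 1.12 CPM. Those that fell most were all oligoadenylate synthetase genes or their kin: Oas2 by 90.9-fold, Oas1g by 75.3-fold, Oas1a by 61.2-fold, Oasl2 by 41.3-fold and Oas3 by 40.5-fold. Oas1g and Oas1a are near copies with fractional counts in 4 libraries, so their separate values are uncertain. Without the third day 7 column Oasl2 moved from -5.37 to -6.66 and Oas3 from -5.34 to -6.27 on the log2 scale, and without the first Oas1g moved from -6.24 to -7.37. On GRCm38, Rbm47 lies on chromosome 5 at 66016549 to 66173118, Tob1 on chromosome 11 at 94211454 to 94215495, Rbpms2 on chromosome 9 at 65629648 to 65660528, Cpeb4 on chromosome 11 at 31872211 to 31935634 and Tfb1m on chromosome 17 at 3519256 to 3557781. Oas2, Oas3, Oas1g and Oas1a are neighbours on chromosome 5, from the start of Oas2 at 120730333 to the end of Oas1a at 120907521, and Oasl2 lies on the same chromosome at 114896936 to 114912234.

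**Figure D3:**
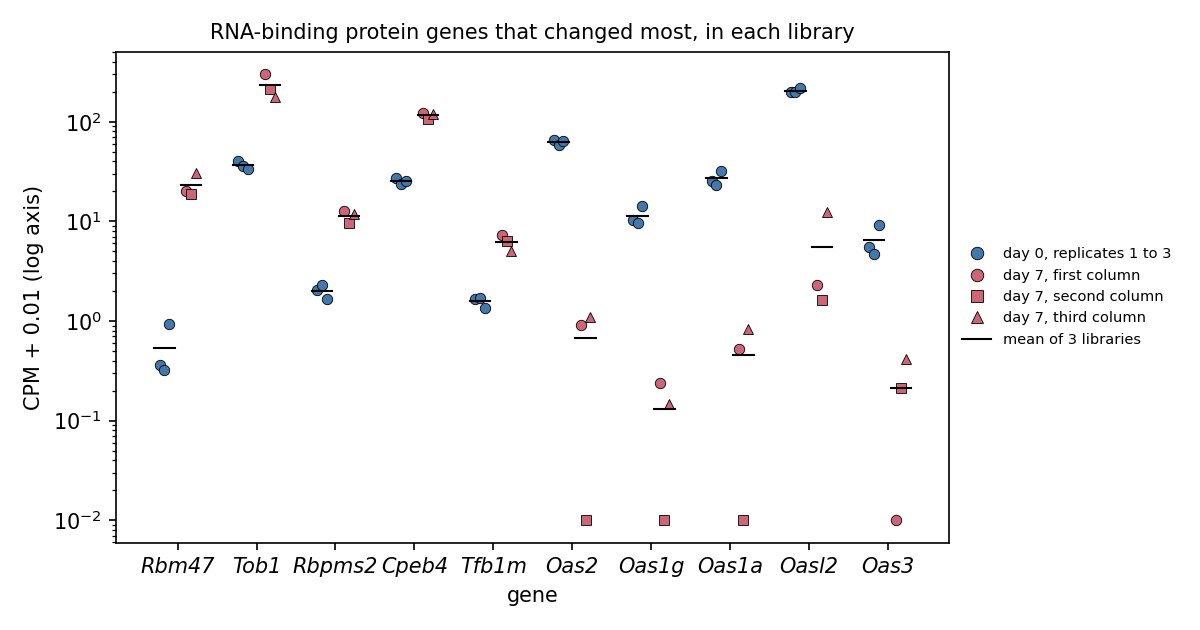
Expression of the 10 RNA-binding protein genes that changed most, as CPM plus 0.01 on a log axis, in each of 3 day 0 libraries (blue) and 3 day 7 libraries (red, with the marker shape giving the column), with a line at each mean. Rbm47, Tob1, Rbpms2, Cpeb4 and Tfb1m lie higher and the Oas genes lower in every day 7 library than in any day 0 library.

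By family, RNA sensors and antiviral proteins, cytosolic ribosomal proteins and mitochondrial RNA-binding proteins moved most uniformly. Of 24 RNA sensors 23 fell and Isg20 rose 1.84-fold, a call lost without day 0 replicate 1 at an edgeR adjusted p of 0.073 (list median log2 fold change -3.61; camera adjusted p = 1.1e-11, but adjusted p = 0.32 with an estimated correlation). The list shares 9 tested members with the interferon-stimulated genes. Of 79 cytosolic ribosomal protein genes 64 fell and none rose, 66 falling when adjusted over the list alone (median -0.88; camera adjusted p = 6.0e-09, but adjusted p = 0.62 with an estimated correlation). Rps20 fell 3.62-fold from 222 ± 19.7 to 61.2 ± 2.11 CPM and Rplp0 2.84-fold from 839 ± 27.1 to 295 ± 11.8 CPM, both with fractional counts in all 6 libraries. Of 33 mitochondrial RNA-binding protein genes 27 rose (median 1.02; camera adjusted p = 4.3e-05, but adjusted p = 0.35 with an estimated correlation), led by Tfb1m and Fastkd1, while Pnpt1, a polynucleotide phosphorylase, fell 1.82-fold and Alkbh1 fell too. Of 25 metabolic enzymes reported to bind RNA, 17 rose and 3 fell (median 1.48; camera adjusted p = 3.9e-06, but adjusted p = 0.32 with an estimated correlation). Fasn, fatty acid synthase, rose 40.1-fold and Hadhb 9.45-fold, while Ass1, Tyms and Shmt2 fell, Hadhb and Ass1 with fractional counts in all 6 libraries, and 8 of the 25 also stand in other lists.

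Splicing families went both ways, and none passed camera's threshold. Of 38 hnRNP genes 13 fell and 5 rose (12 and 5 adjusted over the list alone; camera adjusted p = 0.31, and fry adjusted p = 0.0055), among them Pcbp4, 3.37-fold lower, Hnrnpa1, 2.53-fold lower with fractional counts in 5 libraries, and Taf15, 1.99-fold higher. Of 70 core spliceosome genes 28 fell and 11 rose (28 and 10 adjusted over the list alone; camera adjusted p = 0.23, and fry adjusted p = 0.027), with Lsm7 and Sf3b4 lower by 2.57-fold and 2.37-fold, the latter with fractional counts in 5 libraries, and Lsm1 1.64-fold higher. By total counts alone, 36 of these fell and none rose. Of 22 SR splicing factors 6 rose and 3 fell (6 and 2 adjusted over the list alone), or 5 and 5 with upper-quartile scaling and 0 and 4 by total counts alone, with Srsf3 1.77-fold lower on fractional counts in 5 libraries. Srrm2 and Rbm39, with log2 fold changes of 0.62 and 0.59, lost their calls without single libraries, at edgeR adjusted p values up to 0.068 and 0.11. Tissue-regulated splicing factors had 9 of 28 higher and 8 lower, or 6 and 9 by total counts alone, Rbm47 and Rbpms2 at one end and Celf5, 8.68-fold lower, at the other.

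Families that set mRNA stability and decay also went both ways. In mRNA stability and AU-rich element binding 19 of 48 rose and 13 fell (20 and 13 adjusted over the list alone; camera adjusted p = 0.69, and fry adjusted p = 0.035), with Cpeb4 and Zfp36, tristetraprolin, up and Larp6, a collagen mRNA binder, 6.78-fold lower. Zfp36 was 25.3 ± 1.02 and 92.8 ± 61.1 CPM, and its log2 fold change moved from 1.87 to 1.27 without the third day 7 column. Of 53 deadenylation, decapping and decay genes 17 rose and 6 fell (17 and 5 adjusted over the list alone; camera adjusted p = 0.62, and fry adjusted p = 0.0090), with Tob1 and Btg2 up and Fam46b, a poly(A) polymerase, 4.06-fold lower, and Btg2 moved from 1.92 to 1.32 without that column. By total counts alone 7 rose and 7 fell. Of 36 DEAD-box and DEAH-box helicases 10 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.31, and fry adjusted p = 0.0032), with Dhx32 3.21-fold and Ddx28 2.59-fold higher, and of 37 RNA modification and editing genes 13 rose and 6 fell (camera adjusted p = 0.69). Among the latter Adar, the interferon-inducible RNA deaminase, fell 5.07-fold from 62.2 ± 6.76 to 12.4 ± 3.49 CPM, while Adarb1 rose 2.07-fold and Alkbh5, an RNA demethylase, 1.84-fold. In small RNA silencing 3 of 17 rose and 4 fell (3 and 3 adjusted over the list alone), with Mov10 2.11-fold lower and Ago3 1.83-fold higher on fractional counts in all 6 libraries.

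Translation and processing families likewise stayed outside camera's threshold. Translation initiation factors had 13 of 43 higher and 6 lower (12 and 5 adjusted over the list alone), with Eif4ebp1, the repressor of eIF4E, 2.49-fold higher and Eif5a2 2.44-fold lower. Elongation and termination factors had 3 of 14 higher and 4 lower (fry adjusted p = 0.047), with Eef1b2 1.82-fold, on fractional counts in all 6 libraries, and Eef1d 1.60-fold lower and Secisbp2 1.78-fold higher. Of 22 aminoacyl-tRNA synthetases 5 rose and 1 fell (4 and 0 adjusted over the list alone), Eprs rising by 1.95-fold and Mars by 1.76-fold. The single one that fell, Tars, 1.24-fold, lost its call without single libraries at adjusted p values up to 0.14 by edgeR. Ribosome biogenesis had 14 of 61 higher and 11 lower (11 and 10 adjusted over the list alone), with Rcl1 3.43-fold and Nop10 2.35-fold higher and Nop58 1.60-fold lower. Polyadenylation and 3' end processing had 6 of 25 higher and 5 lower, with Pabpc4 1.74-fold higher on fractional counts in all 6 libraries and Slbp, the histone mRNA stem-loop binder, 1.78-fold lower. The exon junction and nonsense-mediated decay list had 10 of 32 higher and 4 lower (9 and 2 adjusted over the list alone), with 1200014J11Rik 1.94-fold and Thoc1 1.62-fold higher. In every family of this and the preceding paragraph except the helicases, scaling by total counts alone left no more rises than falls. For the helicases it left 4 rises and 2 falls, and their median log2 fold change turned from 0.18 to -0.05. Fry was run with TMM scaling only, so its calls for these families were not tested under other scalings.

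**Figure D4:**
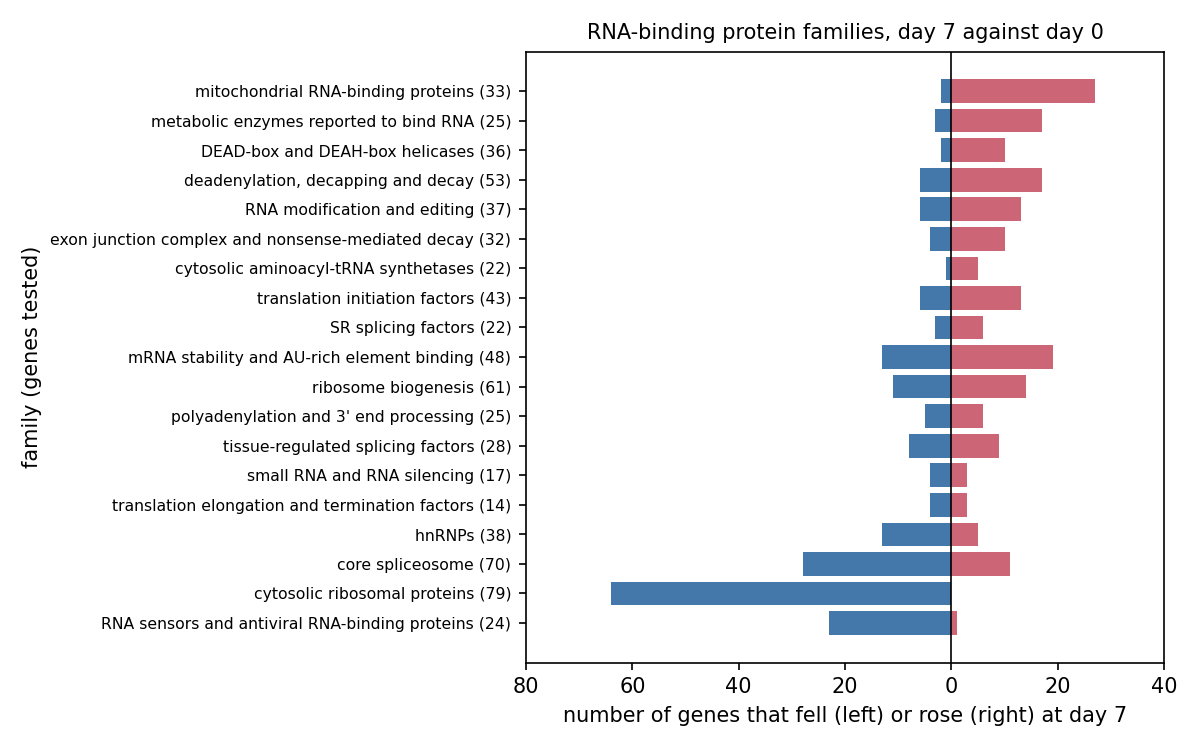
Number of genes that rose (red, right) and fell (blue, left) at day 7 in each RNA-binding protein family (edgeR adjusted p under 0.05), with the number tested in brackets. Mitochondrial RNA-binding proteins show 27 rises and 2 falls, and cytosolic ribosomal proteins 64 falls and no rise.

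Other lists did not pass camera's threshold, though fry, which tests a list against no change and not against other genes, called glucocorticoid and cAMP targets (adjusted p = 0.039), the unfolded protein response (adjusted p = 0.0088) and abundant RNA genes (adjusted p = 0.033). Glucocorticoid and cAMP targets had 11 of 16 higher (camera adjusted p = 0.14), with Zbtb16, a glucocorticoid-induced factor, 312-fold and Fos 5.61-fold higher, and passed at 0.0042 without the second day 7 column, 0.025 by total counts alone and 0.027 without the filter on low counts. Lcn2, from 559 ± 67.4 to 61.8 ± 94.0 CPM, lost its call without single libraries (edgeR adjusted p up to 0.10), and its log2 fold change moved from -3.20 to -6.13 without the third day 7 column. Immediate early genes had 9 of 15 higher (camera adjusted p = 0.35, or 0.0027 without the second day 7 column), with Egr2 at 1.52 ± 0.135 and 18.4 ± 15.5 CPM, and its log2 fold change moved from 3.57 to 2.76 without the third day 7 column. Immediate early genes and glucocorticoid and cAMP targets share 3 tested members, Dusp1, Fos and Nr4a1, so these lists are not independent. The unfolded protein response list had 11 of 25 higher and 5 lower, with Dnajb9 5.50-fold and Trib3 3.73-fold higher and Manf 2.02-fold lower. Basement membrane genes had 7 of 15 higher and 2 lower, Lamb3 10.7-fold and Col15a1 5.09-fold higher and Agrn 5.91-fold lower, and without the third day 7 column Col15a1 moved from 2.35 to 1.69 on the log2 scale. Of 12 abundant RNA genes 4 rose, Neat1 by 6.87-fold, Malat1 by 5.86-fold, mt-Rnr1 and mt-Rnr2.

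Markers of other cell types were mostly below the filter. Of 16 macrophage markers only Cd14 was tested, and it fell from 10.5 ± 0.34 to 2.59 ± 1.65 CPM. Of 13 endothelial markers Eng, Egfl7 and Flt1 were tested, and Eng fell 2.61-fold. Of skeletal muscle markers Des rose 7.92-fold to 23.8 ± 2.91 CPM, and of epithelial markers Krt18 went from no counts to 66, at least 24.9-fold. Of 4 tested bone and cartilage markers Sox9 fell 8.89-fold, Runx2 fell and Spp1 went from 423 ± 88.6 to 82.4 ± 71.7 CPM, while Alpl at 2.77 ± 0.289 and 12.6 ± 13.98 CPM lost its call without single libraries (edgeR adjusted p up to 0.12). The log2 fold change of Alpl moved from 2.12 to 0.78 without the third day 7 column. That of Spp1 moved from -2.37 to -3.34. None of 8 haemoglobin and serum genes passed the filter.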

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

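The number of genes changed ranged from 6125 to 8229 with 1 library left out, and from 5248 to 7725 under other scalings, filters and tests. Tested against a 2-fold change, 2758 genes changed, 1275 up and 1483 down, with 53 RNA-binding protein genes, 20 up and 33 down, since a larger change is asked for. With total counts as scaling 2355 genes rose and 65 RNA-binding protein genes rose, and their log2 odds of rising reversed from 0.25 to -0.50 (Fisher's exact p = 0.023); the median of all genes moved from 0.02 to -0.21. Without a low-count filter their log2 odds of changing reversed from -0.52 to 0.50 (Fisher's exact p = 3.1e-05), as 20807 genes were tested and the added genes, few of them RNA-binding, had few counts. With 1 library left out, 112 to 203 RNA-binding protein genes rose, and the log2 odds of rising ranged from 0.066 to 0.43 (Fisher's exact p = 0.0063 without the third day 7 column); the cause was not tested. With an estimated correlation 2 of 23 lists stayed past the threshold, and fry, which asks whether a list changed at all and not whether it differs from other genes, called 32. Of 2024 values for 137 named genes under alternatives 1941 kept their direction and side of the threshold, 83 lost the threshold and 0 reversed. Most of these genes were named for passing the threshold with large changes, so this share does not hold for all genes. Of the 7413 calls over all genes, 5949 were kept by total counts, 6013 without day 0 replicate 1 and 7346 with RLE. Of 702 values for 44 lists 668 stayed, 21 lost it, 13 gained it, 9 of them with fry and its different question, and 0 reversed. No paired analysis was possible because the day 7 columns carry no distinct replicate numbers, so the planned replicate block was not run. Alternatives planned for normalized values, other pseudocounts and no filter on low values, do not apply because the table holds counts. Depth limits fold changes of genes with few counts in a group. Those with 3 counts or fewer over a group are given as bounds or wide intervals. Genes with slightly more have folds without an interval that rest on few counts. Examples are Oas3, with 0, 2 and 3 counts in the day 7 columns, and Zbtb16, with 3, 1 and 2 at day 0.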

Other observations

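The tests of immune cell content and of scaling were chosen only after the results were seen, the first after an earlier limit of 1 CPM was not met and the second in place of an earlier one that subtracted the all-gene median and so could not depend on scaling, and the other tests were written before their results. Genes on no list also changed, and those named here were chosen after their values were seen. Sort1, a sorting receptor of glucose transporter vesicles, rose from 4.12 ± 0.304 to 170 ± 34.2 CPM (SD, n = 3 per day; edgeR adjusted p = 3.1e-06), and Hsd11b1, which activates glucocorticoids, rose from 2.77 ± 0.566 to 63.1 ± 3.57 CPM (adjusted p = 3.1e-06). Ero1l, an oxidase of the endoplasmic reticulum, rose from 116 ± 5.67 to 2168 ± 506 CPM (adjusted p = 9.0e-06). Pcdh18, a protocadherin, fell from 122 ± 16.8 to 7.47 ± 3.40 CPM (adjusted p = 2.5e-05), and Atp1b1, a sodium pump subunit, fell from 97.4 ± 4.92 to 5.45 ± 2.57 CPM (adjusted p = 2.8e-05).

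Cytosolic ribosomal protein genes were lower at day 7 (median log2 fold change -0.88). The median was -0.9055 (95% interval -0.9936 to -0.8544) once a trend on summed exon length was removed, so this length does not account for it. That length covers all annotated exons, with a list median of 1770, and may exceed the transcripts' own, so a bias on transcript length stays open. Other genes under 1000, outside oxidative phosphorylation, had a median of -0.17. The 95% intervals of list medians here and below resample genes as if independent. Reads shared with pseudogenes could lower single genes, but the 6 members with whole counts had a median of -0.7817 (-1.141 to -0.6113). Under the 4 other scalings tried the list's median lay between -1.118 and -0.8904 (95% interval of the latter -0.9378 to -0.8143). These scalings moved the median of all genes from 0.022 only to between -0.207 and 0.014, none of them upward. They thus could not have lifted the list's median, and an error common to all scalings was not tested. A hypothesis that mRNAs with a 5' terminal oligopyrimidine tract fall as a class was tested on 23 other genes of this kind, of which 15 fell and Eif4a2 and Eef1e1 rose. Their median was -0.6529, below the 95% range of -0.3547 to 0.4604 of 10000 random lists matched on expression (one-sided p over random lists = 0.00070). Without 3 genes already seen it was -0.58 (one-sided p over random lists = 0.004). These genes may not be independent, and such p-values do not measure the spread between samples.

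Interferon-stimulated genes were high at day 0, which could come from immune cells in the culture. Summed CPM of 9 leukocyte transcripts was 0.02893% (0.02284% to 0.0359%) of that of the interferon-stimulated genes at day 0, or 1.30 ± 0.294 CPM (SD, n = 3), with 47 counts from Csf1r and Aif1 and 3 from the other 7, which argues against it. Cd14, the macrophage marker past the filter and not in that sum, was at 10.5 ± 0.34 CPM at day 0 and fell 4.27-fold. Under the 4 other scalings tried the list medians lay between -3.329 and -3.13 (95% interval of the latter -4.381 to -2.601). As these scalings moved the median of all genes little and never upward, they could not have brought this list near no change. An error common to all scalings was not tested. No day 7 library carried the result alone: the highest of the 3 medians was -2.334, in the third column.

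The third day 7 column stood apart, which may reflect undifferentiated cells in it. Of 148 genes with enough counts among 532 at least 8-fold lower in the other 2 columns, 53.38% had an excess within 2-fold of the median share of 7.37%, so mixing stays open. Shares, the excess over the mean of the other 2 as a part of that of day 0, were uneven: 73.3% for Prl2c2, 61.5% for Cp and 49.0% for Cxcl1, while Tnc, Apod and Sfrp2 lay below the mean of the other 2 columns. Lower depth is argued against as the cause, since after thinning the other 2 to its depth their correlation with each other exceeded that with the third by at least 0.01943 over 10 thinnings.

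Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split was the only 1 to reach its count of genes changed, 7413 against a highest other of 0, of RNA-binding protein genes, 310 against 0, and of lists, 23 against 22. At an unadjusted p under 0.05 the other 9 splits gave 24 to 90 genes and the real one 7938. Lists past the camera threshold, 17 to 22 in the other splits, were thus nearly as many where no gene passed. Every other split put libraries of both days in each group, so the day difference widened the spread within groups. Few gene calls were thus fixed in advance, and the lists still carried part of the day difference. These splits therefore cannot say what a grouping without any difference would give.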
